A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

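Poly(A)-selected RNA of 4 *Saccharomyces cerevisiae* strains was sequenced after a temperature shift, with 1 library per genotype. Per the labels, the genotypes were wild type (WT, strain BJ2664), mtr3-1 (strain T208), mtr4-1 (strain T188) and dis3^mtr (strain T186, also called rrp44-1 or mtr17-1). Cultures grew in rich medium at 30 °C to an OD600 of 0.4 and were then held at 37 °C for 2 h. Per the labels' protocols, each library carried a barcode of 3 bases, and the libraries were run together in a single Illumina GAIIx lane for 36 cycles. The submitters' processing notes name Bowtie and the genome build sacCer2. The Bowtie version, the treatment of reads matching several places and the way reads were assigned to genes are not given in the sources used here.

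The deposited tables cover 16 GO terms chosen by the authors around tubulin, microtubules, the spindle and mitosis. Each entry holds a gene, a position in kb, a value per library that the authors called a normalized numerical value, and that value as a percent of WT. How the values were normalized is not given in the sources used here, so they were used as ratios between libraries of the same gene. Genes were ordered by mean level only for an SD of the lower genes and for a correlation with level. Per the file headers, the authors called a gene increased at 115% of WT or more and decreased at 85% or less, and averaged the percents within a term. The deposited percents equalled 100 times the mutant value over the WT value, with a largest deviation of 1.1e-13. All 48 term averages lay within 0.01 of the mean recomputed from the entries. The authors' increased and decreased counts equalled the recounted ones in 41 of 48 term and mutant pairs, and in 45 of 48 when the percents were first rounded to whole numbers. Entries without values occurred in 24 of these pairs, and in 18 of them the authors' unchanged count included those entries.

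Of 190 entries, 175 held values and 15 held none. They named 144 ORF identifiers, of which 133 had values, and these formed 130 distinct sets of values. The term tables are a selection made by the authors, and genes outside them are not analysed here. Names and coding lengths were taken from the R64 annotation, in which 141 of the 144 identifiers were found. That build differs from the authors' build, so printed positions are the authors' kb positions on sacCer2, and R64 served only for an approximate check with a tolerance of 1 kb. For 9 of the 130 features the identity was uncertain, because the name and position disagreed, the ORF had no entry in R64, or another gene carried the same values. These were YDR118W-A (listed as APC4), YFR036W-A (listed as CDC26), SKP1 and BNI5 (positions exchanged), CEP3 and GIN4 (positions exchanged), CBF2 (same values as KCC4), DMA2 (same values as CTF13) and GLC7 (listed at another position). The other 121 were treated as certain, including 3 with a differing chromosome number at the same kb position.

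Each mutant was compared with WT by the deposited percents and the authors' thresholds. With 1 library per genotype no test across samples exists, and no p-value or spread between replicates is given. The SDs and resampling ranges given are spreads across genes. The depth per library is unknown, because the values are not counts, so no counting error could be attached either. Each genotype came from its own strain, so strain background and genotype cannot be separated. Overlaps between mutants were set beside the overlap of independent lists, n1 × n2 / N with N = 130, and beside lists of the same sizes drawn from 1000 simulations of unchanged libraries that share a WT library, with equal normal errors in each library. This reference was added after seeing the data. Correlations between mutants were set beside 1000 simulations of 3 unchanged libraries measured against the same WT library, with a per-library SD of 0.36 on the log2 scale. That SD was taken from the spread between mtr3-1 and mtr4-1, which also holds any real differences between them. Fisher's exact test, planned as a description of the overlaps, was not run, since all comparisons share the WT library. Correlations were computed across genes, which are not independent replicates.

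Before the data were examined, 21 gene lists were fixed, and a rule for naming genes was written. It takes the 10 highest and 10 lowest genes per mutant, up to 4 examples per list, TUB1, TUB2 and TUB3, and allows any table of at most 30 genes to be named in full. Of the lists, 5 had measured members: tubulins and tubulin folding, microtubule motors and plus-end proteins, spindle pole body, kinetochore and spindle checkpoint, and mitotic cyclins and mitotic regulators. The other 16 lists, which covered exosome subunits and cofactors, ribosome, stress and metabolic genes among others, had no measured member and are not analysed here. Since values of a selected set of genes were held, list results are counts and medians over measured members, with no comparison to random lists. Each of the 5 lists was fixed with more genes than were measured, and its other genes are not covered.

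The alternatives tried were thresholds of 1.5-fold and 3-fold, pseudocounts of 0.1 and 5, a minimum value of 5 in the higher library, division by the median of the listed genes, each gene counted once, 3-fold overlaps, a pseudocount of 1 on the log2 scale between mutants, means in place of medians, and terms with at least 5 entries only. Leaving out uncertain identities, term medians, terms without their highest entry, lists with certain identities only, and division by the median of list medians, term averages, ratios between mutants and sets shared by or particular to mutants were chosen after seeing the data. The trend of log2 ratios on coding length was fitted by least squares on the 121 certain features. The code was tested on simulated data. Of 130 simulated genes, the 20 doubled and the 15 halved ones were recovered with 0 others called, and a length slope of 0.4 was recovered as 0.42. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.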

Results

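Transcript levels were measured by sequencing poly(A)-selected RNA from 4 yeast genotypes after 2 h at 37 °C. The 3 mutants carry lesions in the RNA exosome, the complex that degrades and trims RNA from its 3′ end, or in a cofactor of it. MTR3 encodes a subunit of the exosome ring, DIS3 (also RRP44) encodes its catalytic subunit, and MTR4 encodes an RNA helicase that works with the nuclear exosome. The series title names microtubule defects in the DIS3 mutant as the subject. The values analysed are those of 16 GO-term tables on tubulin, spindle and mitotic genes, with 130 distinct features, each given as a normalized value per library and as a percent of WT. There was 1 library per genotype and no replicate, so no difference below could be set against replicate error, and the depth behind each value is unknown. The transcripts of MTR3, MTR4 and DIS3 themselves are not analysed here.

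In dis3^mtr, CDC20, which encodes an activator of the anaphase-promoting complex, was at 564% of WT (chromosome 7, 289 to 291 kb, sacCer2), against 76.3% in mtr3-1 and 84.0% in mtr4-1. Other high transcripts were GIC1, an effector of the GTPase Cdc42 (499%, chromosome 8, 221 to 222 kb), and CIN1, a tubulin-folding cofactor (461%, chromosome 15, 989 to 992 kb). HSL1 and HSL7, which act together in the morphogenesis checkpoint on Swe1, stood at 399% and 314%. Among the low transcripts, URM1, a ubiquitin-like modifier, was at 29.8% of WT (chromosome 9, 342 kb), and CHS1, a chitin synthase, was at 33.7% (chromosome 14, 276 to 279 kb). The histone H3 genes HHT2 and HHT1 were at 30.9% and 43.2%. How any reads matching both genes were treated is not given in the sources used here.

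The same library had high values for several spindle checkpoint genes. BFA1, part of the inhibitor of the mitotic exit network, was at 395% and BUB3, a spindle assembly checkpoint protein, was at 337%. DOC1 and APC1, subunits of the anaphase-promoting complex, were at 304% and 295%. The highest percent in the tables, 1048% for YFR036W-A, which is listed under the name CDC26, rested on a WT value of 0.376 and has no certain identity. CDC26 under its own identifier was at 119%. At the low end GIM4 and YKE2, subunits of the tubulin-binding prefoldin complex, were at 38.1% and 43.4%, RBL2, which binds β-tubulin, at 38.2%, and LDB18, a dynactin component, at 42.2%. GLC7, the lowest in the tables at 14.7%, and SKP1, at 44.7%, have positions that disagree with their names.

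Of the 175 entries with values, 88 were at 115% of WT or more in dis3^mtr and 35 at 85% or less. With each feature counted once, the numbers were 61 and 30 of 130. Division by the library's median over the 130 features brings the features near balance by construction. It gave 67 and 48 entries, in which genes of several terms are repeated, but 47 and 41 features. Among the 130 features, 25 were at least doubled and 10 were at 50% or less. The median feature was at 112% of WT, a log2 shift of 0.17. Across the 121 certain genes, the log2 ratio in dis3^mtr was positively correlated with coding length (Spearman's rho 0.34; genes are not independent replicates). Ratios to WT were negatively correlated with a gene's mean level over the libraries, with rho -0.23, -0.34 and -0.29 in mtr3-1, mtr4-1 and dis3^mtr. High percents thus tended to go with low levels.

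By the lists fixed before the data were examined, microtubule motors and plus-end proteins had the highest median in dis3^mtr, 180% of WT over 10 measured members, with 6 at 115% or more and 2 at 85% or less. KIP3, a kinesin that shortens microtubules, was at 285%, ARP1, a dynactin subunit, at 267%, CIK1, the partner of the kinesin Kar3, at 260%, and the dynein heavy chain DYN1 at 239.9%. The kinetochore and spindle checkpoint list had a median of 162% over 11 measured members. Of these, 7 were at 115% or more, including CBF2 and CEP3 of uncertain identity. Over the 9 certain members the median was also 162%, with 5 at 115% or more. Only MAD2, a checkpoint protein, was at 85% or less in that list, with 65.5%, while BUB1 was at 251% and BUB2 at 217%. The percent of BUB1 rested on a low WT value of 2.85. Of 10 mitotic cyclins and regulators, 6 were at 115% or more, among them the B-type cyclin CLB2 at 201% and CDC20, and the median was 124%. After division by the median of the listed genes, 4 of the 10 were at 115% or more and the list's median was 109.8%, inside the thresholds. CLB1, the close relative of CLB2, was at 75.7%. Of the spindle pole body list, only 3 genes were measured: SPC72 at 81.5%, SFI1 at 88.1% and MPS1 at 106%. Their median moved from 88.1% to 78.4% with the same division.

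The tubulin genes themselves were above the thresholds only in dis3^mtr. TUB2, the single β-tubulin gene, was at 152% of WT there, and the α-tubulin genes TUB1 and TUB3 were at 138% and 122%. In mtr3-1 the corresponding values were 105%, 105% and 98.3%, and in mtr4-1 they were 106%, 97.3% and 70.4%. After division by the median of the listed genes, TUB3 in dis3^mtr was at 109%, inside the thresholds, and TUB1 and TUB2 in mtr4-1 were at 119% and 131%. The tubulins and tubulin folding list had 11 measured genes. In dis3^mtr, 4 of them were at 115% or more and 5 at 85% or less (3 and 6 after division). Their median was 94.5% (84.0%). CIN1 was the member at 115% or more in every mutant.

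In mtr3-1, GIC1 was at 522% of WT, CIN1 at 369%, BFA1 at 327% and HSL1 at 267%. DMA1, a ubiquitin ligase of the spindle position checkpoint, was at 246%, followed by GIC2, a relative of GIC1, at 211%, BUB2 at 201%, CDC23 at 195% and ARP1 at 193%. The low end was led by histone H3, with HHT1 at 26.7% and HHT2 at 29.7%, and by CLB1 at 34.5% (chromosome 7, 703 to 705 kb). All 6 entries of the term for chaperones of tubulin complex assembly lay below 85%: YKE2 at 43.9%, RBL2 at 45.0%, PAC10 at 48.1%, GIM4 at 58.7%, GIM5 at 70.2% and GIM3 at 73.5%. BIM1, a protein of microtubule plus ends, was at 47.9% and URM1 at 58.1%. GLC7 at 40.2% and SKP1 at 41.8% have uncertain identities, as does YFR036W-A at 449%.

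Entries on either side were equally many in mtr3-1, with 56 at 115% of WT or more and 56 at 85% or less. With each feature counted once, 36 and 43 of 130 passed. The median feature was at 99.2%. The kinetochore and spindle checkpoint list had 6 of 11 members at 115% or more, including CBF2 of uncertain identity, and 3 at 85% or less, with a median of 123%. The tubulins and tubulin folding list had 7 of 11 at 85% or less and a median of 73.5%, although its mean was 99.2% because of CIN1. Motors and plus-end proteins had 4 of 10 on each side, and mitotic cyclins and regulators had 1 of 10 at 115% or more, CDC15 at 140%, and 4 at 85% or less. In the spindle pole body list SPC72 was at 63.7%, SFI1 at 80.1% and MPS1 at 104%. The log2 ratio was correlated with coding length across genes in this library too (rho 0.40), and the chaperone genes are short.

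In mtr4-1, BFA1 was at 480% of WT, CIN1 at 329%, GIC1 at 268% and HSL1 at 198%. The checkpoint genes BUB3, BUB2 and BUB1 were at 192%, 180% and 156%, BUB1 on a WT value of 2.85, and CIK1 was at 152%. Among the lowest were TGL4, which encodes a lipase, at 39.5% (chromosome 11, 605 to 608 kb), BIM1 at 43.1% and MOB1, an activator of a mitotic exit kinase, at 47.4%. RSC6, a subunit of the chromatin remodeler RSC, was at 47.8%, CLB1 at 49.9%, CHS1 at 50.1%, UBA4, the enzyme that activates Urm1, at 50.8% and BIK1, a protein of microtubule plus ends, at 52.3%. GLC7 at 25.5%, SKP1 at 47.5%, CBF2 at 159% and YFR036W-A at 793% have uncertain identities.

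More entries were low than high in mtr4-1: 97 of 175 were at 85% of WT or less and 28 at 115% or more. The median feature was at 81.5%, a log2 shift of -0.30. Division by that median brings the features near balance by construction. The counts were then 55 low and 62 high entries, or 44 low and 43 high features. Whether the shift comes from the scaling of the library is not known, because the normalization is not given in the sources used here. The kinetochore and spindle checkpoint list had 6 of 11 members at 115% or more, including CBF2 of uncertain identity, and a median of 129% (158% after division). Of its members 3 were at 85% or less: BIR1, an inner centromere protein, at 59.0%, MAD2 at 63.9% and MAD3 at 77.3%. The tubulin and tubulin folding, spindle pole body, and mitotic cyclin lists had medians of 81.9%, 81.8% and 81.9%, which moved to 100.5%, 100.4% and 100.5% after division. Motors and plus-end proteins had a median of 98.4%, or 121% after division.

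**Figure D1:**
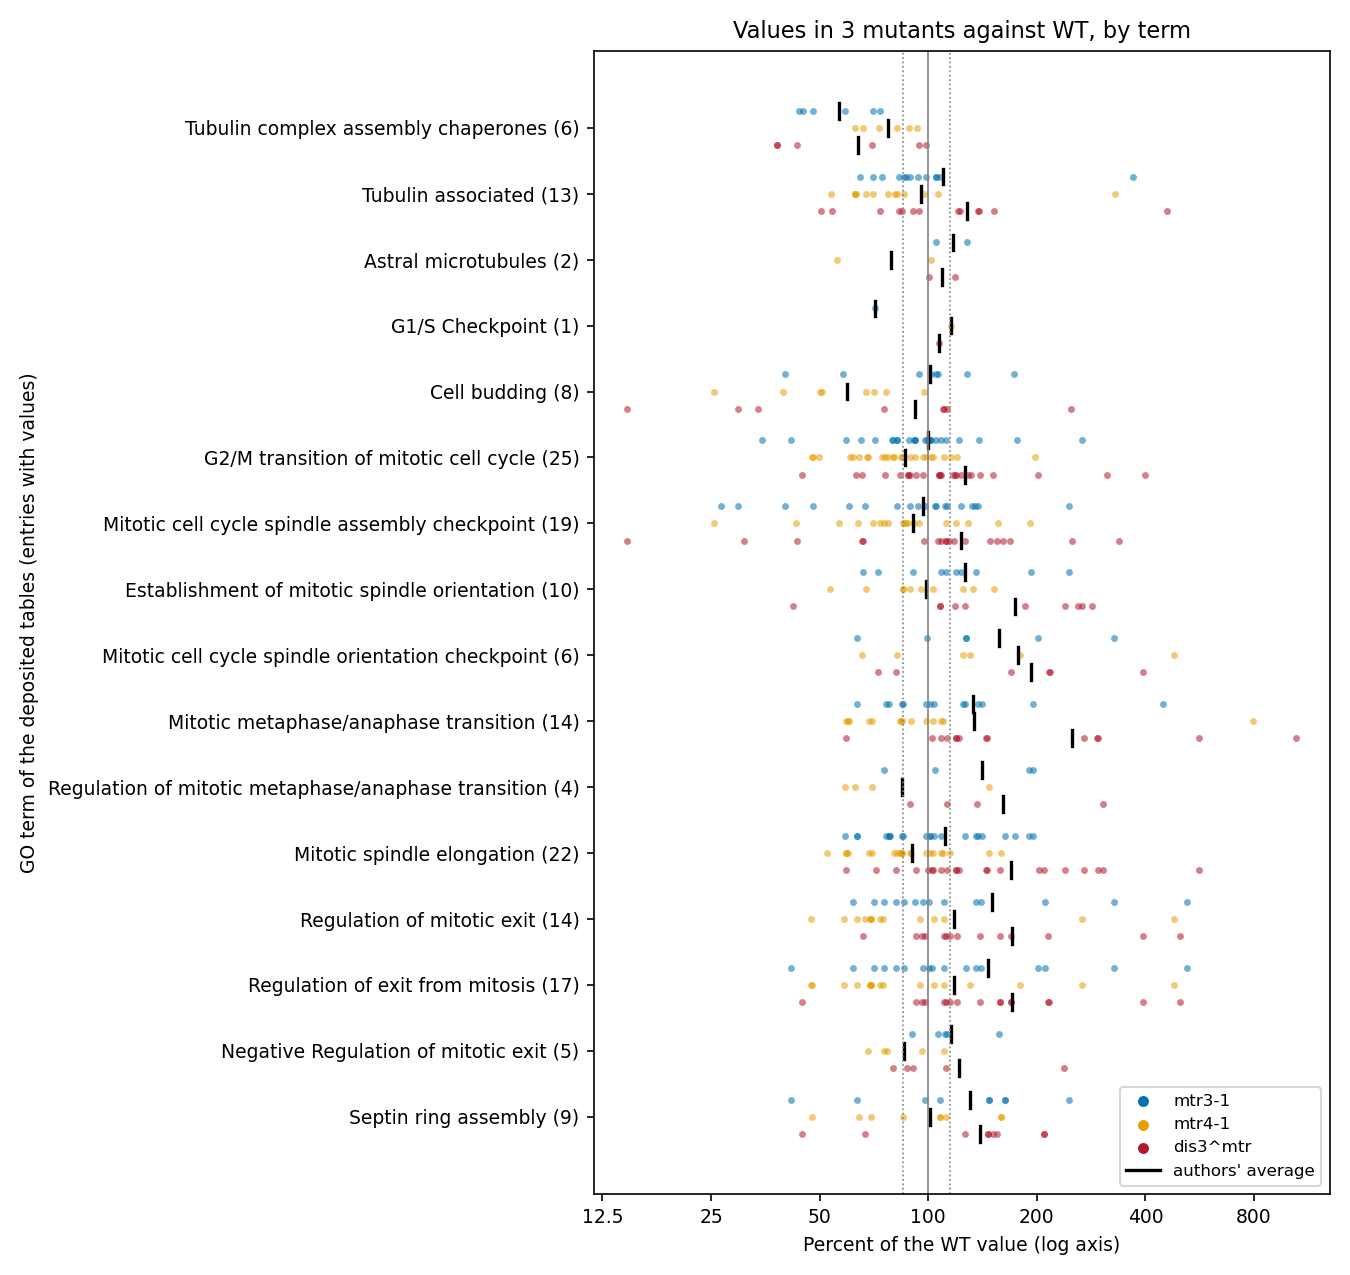
Percent of the WT value on a log axis for each entry with values (points) in the 16 GO terms, by mutant, with the authors' average as a black bar; dotted lines mark 85% and 115%. In the chaperone term the averages sit at 56.6%, 77.5% and 63.8% in mtr3-1, mtr4-1 and dis3^mtr, and in the metaphase/anaphase term the dis3^mtr average of 250.2% is drawn up by a point at 1048%.

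By term, the authors' deposited averages were at 115% or more in 12 of the 16 terms in dis3^mtr, 9 in mtr3-1 and 5 in mtr4-1. The terms are not separate, since 39 of the 130 sets of values sat in more than 1 term. In addition, 3 terms had fewer than 5 entries with values. By term medians the numbers were 8, 5 and 2. After division by the median of the listed genes they were 8, 9 and 8, so the contrast between dis3^mtr and mtr4-1 did not hold under that scaling. The term for mitotic metaphase/anaphase transition had the highest one, 250.2% in dis3^mtr, but its median entry was at 133%, and without YFR036W-A the mean was 189%. Mitotic spindle elongation averaged 169% in dis3^mtr with a median of 120.4%, and CDC20 was its highest entry. The spindle orientation checkpoint term, with BFA1, BUB2, KIN4, LTE1, RTS1 and SPC72, averaged 157%, 177% and 192% in mtr3-1, mtr4-1 and dis3^mtr, and 124%, 117% and 152% without BFA1. Establishment of spindle orientation, which holds KIP3, DYN1 and ARP1, averaged 174% in dis3^mtr, 127% in mtr3-1 and 98.8% in mtr4-1. The chaperone term had averages of 56.6%, 77.5% and 63.8% in mtr3-1, mtr4-1 and dis3^mtr. After division by the median of the listed genes it was at 57.0% in mtr3-1 and 56.7% in dis3^mtr, but at 95.1%, inside the thresholds, in mtr4-1. Cell budding averaged 59.7% in mtr4-1, with GLC7 the lowest entry.

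BFA1, BUB2, CIN1, GIC1 and HSL1 were at 150% of WT or more in all 3 mutants, on WT values from 4.13 for BFA1 to 16.8 for HSL1. CBF2 and YFR036W-A, of uncertain identity, also were. At the authors' thresholds, 17 features were high in all 3, including ACT1, the actin gene, at 123%, 133% and 119% in mtr3-1, mtr4-1 and dis3^mtr. After division by the median, 16 of the 17 stayed high in all 3, and ACT1, at 106% in dis3^mtr, did not. The 16 features low in all 3 included HHT1, HHT2, URM1, YKE2, RBL2, BIM1, CLB1, MAD2 and APC5. Of these 16, 11 stayed low in all 3 after division, and HHT1 and RBL2 were among those that did not. Features at 115% or more were shared by mtr3-1 and mtr4-1 in 17 cases, by mtr3-1 and dis3^mtr in 29 and by mtr4-1 and dis3^mtr in 18. Independent lists would share 5.26, 16.9 and 8.92. Features at 85% or less were shared in 37, 17 and 27 cases, against 24.8, 9.92 and 17.3. Independence is not the right reference here, because every comparison used the same WT library.

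Simulated unchanged libraries that share a WT library, with lists of the measured sizes, shared 11.1, 25.7 and 14.7 high features and 34.2, 17.9 and 24.8 low ones for the same pairs. The 17 high features shared by mtr3-1 and mtr4-1 lay above the central 95% of those simulations, 7 to 15, and the other 5 overlaps lay inside theirs. Several overlaps were compared, and the simulations gave every gene the same error. The single excess therefore does not show a response shared by those mutants. The log2 ratios were correlated across genes with Pearson's r of 0.70 for mtr3-1 and mtr4-1, 0.72 for mtr3-1 and dis3^mtr and 0.70 for mtr4-1 and dis3^mtr, against 0.50 in the simulated libraries (Spearman's rho 0.60, 0.66 and 0.60). The simulated 0.50 follows from equal error in WT and the mutants, so a WT library with more error would raise it. These correlations therefore do not show a response shared by the mutants. At a 3-fold threshold the shared high features numbered 3, 4 and 3.

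**Figure D2:**
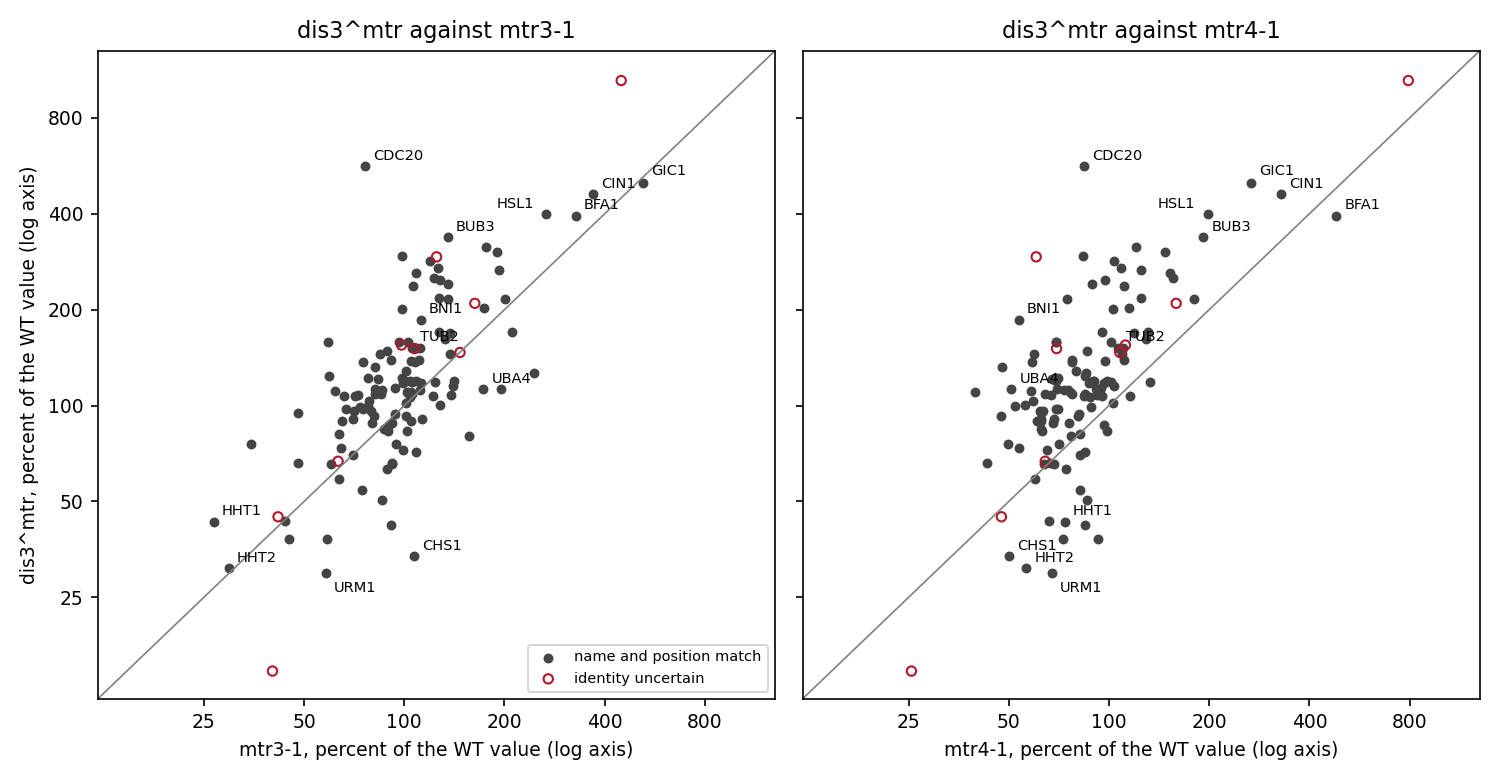
Percent of the WT value in dis3^mtr against mtr3-1 (left) and mtr4-1 (right) for 130 features, on log axes; each point is a feature, open circles have an uncertain identity, and the line marks equal values. CDC20, at 564% in dis3^mtr, lies far above the line in both panels, and CHS1, at 33.7%, lies below it.

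Set directly against the other mutants, without WT, dis3^mtr had more high than low values. Its value was at least 1.15 times that of mtr3-1 for 72 of 130 features and at most 0.85 times for 25, with a median ratio of 1.23. Against mtr4-1 the numbers were 97 and 15, with a median ratio of 1.40. A single scaling factor of the dis3^mtr library would produce such an excess, and after division by the median ratio the sides were near balance by construction, with 40 and 44 features against mtr3-1 and 44 and 38 against mtr4-1. CDC20 was at 88.1 normalized units in dis3^mtr, 11.9 in mtr3-1 and 13.1 in mtr4-1. KIP3 was at 45.6, 19.1 and 16.6 units in the same order, APC1 at 27.5, 9.2 and 7.8, and CLB2 at 23.9, 11.7 and 12.2. Lower in dis3^mtr than in the other mutants were CHS1, with 60.3, 191 and 89.7 units, URM1, with 65.9, 129 and 149, and LDB18, with 35.6, 76.7 and 71.6. In all, 31 features were at 115% of WT or more in dis3^mtr alone, among them CDC20, CLB2, CLB3, CLB4, ESP1, TUB1, TUB2 and TUB3, against 7 in mtr3-1 alone and 1, DDC1, in mtr4-1 alone. After division by each library's median, 12 of the 31 stayed high in dis3^mtr alone, among them CDC20, APC1 and BNI1, against 7 in mtr3-1 alone and 8 in mtr4-1 alone. CLB3, CLB4 and TUB3 were then inside the thresholds in dis3^mtr, and CLB2, ESP1, TUB1 and TUB2 were high in mtr4-1 as well. These differences were not tested, and each mutant came from a different strain.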

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

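Tests of an ordinary error in WT, of strain background and of other short genes were chosen after the result was seen. In 4 features a value at least 1.5-fold above WT in a mutant met a value at least 1.5-fold below WT in another. With 1 library each, the difference was not tested, and after division by the median of the listed genes 2 of the 4, BNI1 and UBA4, still met this condition. BNI1, a formin that nucleates actin cables, was at 186% of WT in dis3^mtr and 53.5% in mtr4-1, a ratio of 3.47. UBA4 was at 173% in mtr3-1 and 50.8% in mtr4-1, a ratio of 3.40. SHE1, a microtubule-associated protein that restrains dynein, was at 158% in dis3^mtr and 58.9% in mtr3-1, a ratio of 2.68. YDR118W-A, listed under the name APC4, was at 293% in dis3^mtr and 60.4% in mtr4-1, a ratio of 4.85, and its identity is uncertain.

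The 32 certain genes at 150% of WT or more in dis3^mtr were weighed against 3 technical explanations. Removing a straight-line trend on coding length left 24 of 32 at 150% or more (23 to 25 over 1000 resamplings of the genes). By the rule set beforehand, fewer than 16 left would have counted for such a trend as the whole cause. The genes were picked for high values in dis3^mtr, so some could stay high even then. The 24 left only equals the number set beforehand, and the resampled low lies below it. In 4 groups of rising coding length, the median in dis3^mtr was 92.7%, 119%, 108% and 166%. A straight line need not remove a rise confined to the longest genes, so a length bias of that shape was not excluded. Dividing the library by its median, 112% of WT, left 26 of 32 (23 to 27 over resamplings). That argues only against a scaling factor of that size as the whole cause. The median comes from genes chosen by the authors, so a larger factor was not excluded. Without WT, 21 of 32 lay at 1.15 times or more the median ratio of dis3^mtr to the mean of the other mutants, between the 16 and the 24 set beforehand, so an error in the WT library cannot be told apart from a difference of dis3^mtr for the set. The dis3 lesion, the strain and an error in the single dis3^mtr library stay open, and none of them was tested.

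BFA1, BUB2, CIN1, GIC1 and HSL1 were at 150% of WT or more in all 3 mutants, on WT values of 4.13, 13.8, 9.23, 8.02 and 16.8. All 5 of 5 lay more than 3 per-library SDs below the mean of the mutants (6.42, 3.20, 6.26, 6.60 and 4.75, with an SD of 0.31 in log2 from the genes below the median level), but they were picked for a low WT value, so these distances alone exclude nothing. In libraries simulated with that SD, 1.63 genes were at 150% or more in all 3 mutants on average, and 22 of 1000 simulations had at least 5; with the SD of 0.36 from all genes, 139 of 1000 had. An error of ordinary size in the WT library was therefore not excluded. The strain background of the WT is a candidate explanation too; with 4 strains for 4 genotypes it cannot be told apart from an effect of the exosome lesions.

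The 6 tubulin-assembly chaperones had a median of 53.4% of WT in mtr3-1. After removal of the length trend of the other genes, 4 of 6 stayed at 85% or less and the median was 71.0%. The 11 other genes of up to 600 coding bases had a median of 91.0% with a lower quartile of 59.2% (28.2% to 94.4% over resamplings), and 2 of them, HHT1 and HHT2, lay at or below the chaperones' median. With so few short genes, a bias by length cannot be told apart from an effect on these chaperones, and the mtr3-1 lesion was not tested.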

How the results depend on the processing

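Of 126 values recomputed under alternatives, 71 kept their level (counts within 1.5 times, list medians on the same side of the thresholds), 51 moved further or across a threshold, and 4 crossed 100% from a list median outside the thresholds. All 4 were in mtr4-1: the tubulin list by its mean and by division, and the spindle pole body and cyclin lists by division. Both pseudocounts, the minimum value of 5 and the log2 scale between mutants left every count they were applied to within 1.5 times. Lower counts follow from stricter thresholds. At 1.5-fold, entries high and low were 28 and 28 in mtr3-1, 16 and 42 in mtr4-1, and 53 and 22 in dis3^mtr. At 3-fold they were 7 and 2, 5 and 2, and 14 and 4. Shared at 3-fold were 3 high and 0 low features for mtr3-1 with mtr4-1, 4 and 1 for mtr3-1 with dis3^mtr, and 3 and 1 for mtr4-1 with dis3^mtr. Counting each gene once lowered the high entries of mtr3-1 to 36, and with certain identities only the high ones were 32, 17 and 55, because fewer items were counted. Division by the median of the listed genes gave 62 high and 55 low entries in mtr4-1. It moved list medians in mtr4-1 to 100.5% for tubulins and tubulin folding, 100.4% for spindle pole body, 100.5% for mitotic cyclins and 121% for motors, and in dis3^mtr to 84.0%, 78.4% and 109.8% for the tubulin, spindle pole body and cyclin lists. As deposited, term averages at 115% or more and at 85% or less numbered 9 and 2 in mtr3-1, 5 and 4 in mtr4-1, and 12 and 1 in dis3^mtr. The division gave 8 terms at 115% or more and 1 at 85% or less in mtr4-1, and 8 and 2 in dis3^mtr. Features high in dis3^mtr alone were then 12, in mtr4-1 alone 8, high in a mutant and low in another 16, and 1.5-fold so 2. Ratios of dis3^mtr divided by their median gave 40 high and 44 low features against mtr3-1, and 44 and 38 against mtr4-1, a balance that the division itself sets. The mean of the tubulin list was 99.2%, 105% and 119% in mtr3-1, mtr4-1 and dis3^mtr, drawn up by CIN1. With term medians, 5 terms were at 115% or more in mtr3-1, 2 in mtr4-1 and 8 in dis3^mtr, with 11 at 85% or less in mtr4-1. Without its highest entry per term, the numbers at 115% or more were 5, 1 and 8, and those at 85% or less were 1, 8 and 2 in mtr3-1, mtr4-1 and dis3^mtr. Terms with at least 5 entries left 1 at 85% or less in mtr3-1 and 2 in mtr4-1. Where no cause is named, the cause was not tested. Identity filters, term medians, left-out highest entries and division of lists, terms, ratios and sets were chosen after seeing the data. An overlap background of all annotated genes, a filter on reads and a p threshold for categories were not run, since the tables hold selected genes without counts or p-values, and no measured gene was in more than 1 list.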

Other observations

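Groups within the tables that were not among the fixed lists, chosen after their values were seen, gave the following values. Of 13 measured subunits of the anaphase-promoting complex, 8 were at 115% of WT or more in dis3^mtr and 1, APC5 at 59.0%, at 85% or less; after division by the median of the listed genes these counts were 5 and 2. DOC1 at 304%, APC1 at 295% and CDC16 at 270.0% stood apart from CDC23 at 113%, APC11 at 109% and APC2 at 102%. The median subunit was at 119%, or 106% after division. In mtr3-1 the highest subunits were CDC23 at 195% and DOC1 at 189.8%, and in mtr4-1 DOC1 at 147% was the member at 115% or more, while 7 were at 85% or less (5 and 4 after division). The 7 measured subunits of the CCT chaperonin, which folds tubulin and actin, were all at 85% or less in mtr4-1, from 53.7% for CCT8 to 81.1% for CCT5, and 5 of 7 were after division by the median. In dis3^mtr they ranged from 73.5% for CCT8 to 137% for CCT4, with 3 of 7 at 85% or less, and also 5 of 7 after division.

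The 5 measured B-type cyclins did not move alike. CLB1 was at 34.5%, 49.9% and 75.7% of WT in mtr3-1, mtr4-1 and dis3^mtr, whereas CLB2 was at 98.2%, 103% and 201%. Of 6 measured subunits of the RSC chromatin remodeler, RSC6 was at 47.8% in mtr4-1 and 132% in dis3^mtr, and RSC4 was at 74.4% and 63.1%. The modifier URM1 was at 58.1%, 67.3% and 29.8% and its activating enzyme UBA4 at 173%, 50.8% and 113% in mtr3-1, mtr4-1 and dis3^mtr. At the authors' thresholds, 26 features were high in a mutant and low in another, among them APC1, CDC20, CDC24, CDC42, CLA4 and NET1. After division by the median there were 16, of which 13 were among the 26; CDC20, CDC24 and NET1 stayed, and APC1, CDC42 and CLA4 did not.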
